A study of Mus musculus with 6 samples.

How the data were processed

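Liver RNA of male mice on a high-fat diet was sequenced in 6 libraries, 3 of the control genotype and 3 of the mutant genotype. Per the labels' protocols, total RNA was column-purified and DNase-treated, poly(A)-enriched libraries were made by a commercial provider, and paired reads of 150 bases were collected on a NovaSeq6000. Per the submitters' processing notes, cutadapt and STAR were used and the genome build was mm10. The program that gave the gene values, the annotation release, the tool versions and the strandedness of the libraries are not given in the sources used here.

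The authors deposited 1 table of estimated counts and 1 table of TPM (length-scaled transcript abundance), each with 55487 genes and a column per library. No deposited nonzero estimated count was whole within a tolerance of 1e-06. Over the 10983 genes with a TPM above 0.5 in every library, the ratio of the deposited estimated count to the deposited TPM followed a fixed factor per gene and a factor per library, with a largest relative deviation of 9.54e-10. The deposited estimated counts are therefore TPM values multiplied by a fixed gene length and a library total, not numbers of reads, and counting error is only approximated by them. Columns were matched to libraries by the sample titles, and 0 columns were left over. Gene coordinates were taken from GENCODE mouse release 21 on the same assembly, in which 99.4% of the gene identifiers were found when the version was ignored.

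Groups followed the titles and genotype labels. No 2 libraries were near-duplicates, since the chi-square between library pairs was at least 47.2 per gene. The labels do not say in words that each library is a separate animal, so p-values measure the spread between these libraries. Library totals ranged from 35847386 to 43162557 estimated counts. Intervals and floors given for low counts cover counting error only, and the floor for a gene with 0 counts in a group was 3 counts over the group.

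Estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr on the group, TMM scaling, the quasi-likelihood F-test on group alone, and Benjamini-Hochberg adjustment over the 14286 genes that passed the filter. A gene was called changed at an adjusted p under 0.05, and changed at least 2-fold where the log2 fold change was also at least 1 in size. Adjusted p-values below are from this test unless another is named, log2 fold changes are mutant against control, and errors of log2 values are standard errors obtained from the F statistic. CPM are estimated counts scaled to library size and are given after TMM scaling as mean ± SD with n = 3 libraries per group. Because TMM sets the level of the typical gene to be equal in both groups, changes are relative to that gene.

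Gene lists were compared with all other tested genes by camera in edgeR with its preset correlation of 0.01, and adjusted over the lists. The camera test with a correlation estimated per list, and fry from limma 3.58.1, were alternatives. There were 34 lists with 722 genes, 11 of them markers of other cell types or neighbouring tissue, and lists with fewer than 3 tested members were not tested. For each list, calls are given over all tested genes and adjusted over the list alone. Shares of counts in gene classes were compared by a two-sided exact permutation test, which cannot go below p = 0.1 with 3 libraries against 3. Principal components used log2 CPM with a prior count of 2 over the 500 most variable genes.

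The tests, the groups, the lists and the naming rule were fixed before the data were examined. Named genes were Rxra, Rxrb and Rxrg. To these were added the 12 called genes with the largest increase, the 12 with the largest decrease, and the 5 with the smallest p in each direction, where the mean CPM was at least 1 in a group, the libraries of the groups did not overlap and the symbol was not a predicted one. From each list up to 4 members with the smallest p were also eligible, without those whose unadjusted p was above 0.05. Of the resulting 142 genes a part is named. Genes named outside the rule are said to be so.

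The alternatives were RLE size factors, library totals without composition scaling, no filter or a CPM filter, DESeq2 1.42.0, robust quasi-likelihood, the replicate number as a block, each library left out in turn, and limma on log2(TPM + 1) and log2(TPM + 0.1) with a TPM minimum of 1 in at least 3 libraries or with no filter. Alternatives added after seeing the data were the summing of multigene families, library totals without the major urinary protein genes, and lists stripped of genes that stand in several lists. The procedure was tested on simulated data with the means and library sizes of this comparison. Over 14286 simulated genes, 45.2% of 104 genes with a 2-fold change and 78.1% of 96 genes with a 4-fold change were recovered, and 8 of 130 calls were false. Only 200 genes were changed in the simulation, against 1923 called in the data, so these shares need not hold for the data. A shifted list was found, and 0 of 33 unshifted lists were called by camera. The simulated genes varied independently and the unshifted lists were random genes. The list result therefore does not test camera's preset correlation on lists whose genes vary together. In the data the estimated correlation reached 0.767, for sinusoidal endothelial markers.

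Genes of families with near-identical copies (Mup, Serpina1, Cyp2, Cyp3a, Cyp4a, Gst, Ugt1a) share reads that the unnamed quantification had to divide, so the values of their single members are uncertain, and sums were tested for the Mup, Serpina1, Cyp2a, Cyp2b, Cyp3a, Cyp4a, Gsta, Gstm, Ugt1a, Hba and Hbb families. No sum was made for Cyp2c or Gstp genes, so that Cyp2c38 and Gstp1 stand as single genes. Overlapping genes cannot be told apart without strand, which holds among the named genes for Hsd3b5 with Zfp697, Pltp with Ctsa, Plin4 with Hdgfl2, Gls2 with Spryd4, Igf1 with Igf1os, Cidea with B430212C06Rik, Rtn4 with Eml6, Oat with Fgfr2, Cxcl10 with Art3, Ccnd1 with LTO1, Stab1 with Nt5dc2, Alas2 with Apex2, Mogat1 with BC035947, Apoa5 with Gm47544, Apoc4 with Gm44805, Retsat with Gm45053, Ciart with C920021L13Rik, Cyp2a4 with Gm42375 and Hsp90b1 with 1810014B01Rik. Figures were drawn with matplotlib 3.10.9.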

Results

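The study compared the livers of male mice with a hepatocyte-directed change of Rxra with those of controls, on a high-fat diet. RXRα, the product of Rxra, is the shared dimer partner of nuclear receptors such as PPARα, LXR, FXR, CAR and PXR, which govern lipid, bile acid and xenobiotic metabolism. The genotype labels give all samples a Cre recombinase transgene under the albumin promoter, which is active in hepatocytes, and the 3 controls that transgene alone. The titles differ from this, since they call the controls WT and only the mutants Cre. For the 3 mutant livers the genotype label adds an Rxra allele marked f/f, whereas the design text names an S65A form of the protein, and gene-level values cannot show which form the transcripts encode. Library totals were 40155170, 38766643 and 38773219 estimated counts for control replicates 1 to 3 and 43162557, 37411747 and 35847386 for mutant replicates 1 to 3. A TPM of at least 1 was reached by 11979, 11948 and 11998 genes in the controls and by 10838, 10567 and 10863 genes in the mutants.

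Gene-level counts cannot show whether part of the Rxra transcript is missing in the mutant livers. Rxra as a whole was still counted there and was not lower after TMM scaling. Its level was 462 ± 44.4 CPM in the controls and 610 ± 88.7 CPM in the mutants (SD, n = 3 each), and the values were 501, 471 and 414 CPM in control replicates 1 to 3 and 700, 522 and 609 CPM in mutant replicates 1 to 3. The difference, a log2 fold change of 0.40 ± 0.13, did not pass edgeR's test (adjusted p = 0.0724). It passed with DESeq2 (adjusted p = 0.0295), with no filter (0.0356) and without mutant replicate 2 (0.0388), and turned to -0.20 in the limma fits on TPM. Before scaling Rxra had 62397 counts over the controls and 62496 over the mutants, so its increase depends on the scaling. Rxrb, a receptor of the same family, had a log2 fold change of 0.35 ± 0.11 that did not pass (adjusted p = 0.0692) and was -0.05 at library totals. Rxrg, the least abundant of the 3, fell by 0.93 ± 0.22 on the log2 scale (7.14 ± 0.937 to 3.75 ± 0.795 CPM, adjusted p = 0.0314), a call that was lost on leaving out any library except mutant replicate 2. In mm10 coordinates Rxra (ENSMUSG00000015846.15) spans bases 27676440 to 27762957 of chromosome 2, Rxrb 34031812 to 34038399 of chromosome 17 and Rxrg 167598384 to 167639623 of chromosome 1.

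The mutant livers differed from the controls on a broad scale. Genes of male-typical secreted proteins such as the major urinary proteins rose, as did 14 of 22 periportal hepatocyte genes, Cps1 of the urea cycle among them. In the other direction, 22 of 30 extracellular matrix genes, 11 of 16 markers of monocyte-derived macrophages and single genes of lipid storage such as Plin4 fell. Of 14286 tested genes, 949 rose and 974 fell in the mutants, together 1923, and 825 of these changed at least 2-fold, with 249 higher and 576 lower. The libraries of the groups did not overlap in 1918 of the 1923 genes, which selection by the test on these libraries largely ensures. Over all tested genes they did not overlap in 34.9%, where chance gives 10%. The leading principal component held 52.4% of the variance and separated the groups, and correlations of log2 CPM were 0.968 to 0.975 among controls, 0.962 to 0.972 among mutants and 0.937 to 0.952 between groups.

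**Figure D1:**
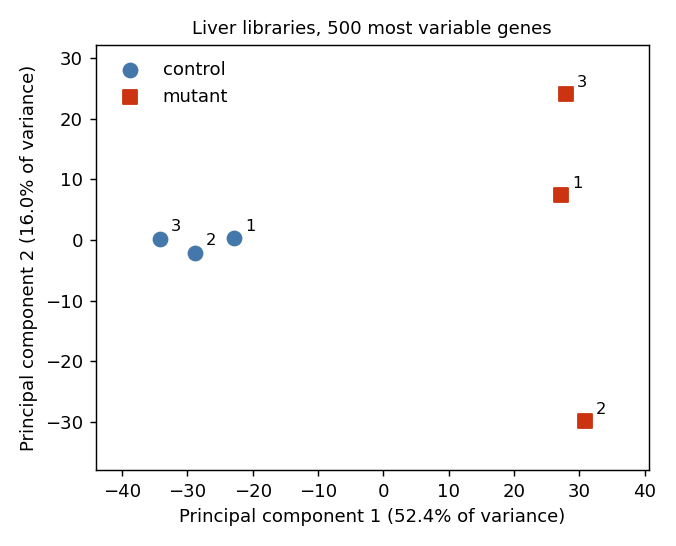
Principal components 1 (horizontal axis) and 2 (vertical axis) of the log2 CPM of the 500 most variable genes, one point per library, circles for control and squares for mutant, with the replicate number beside each. Controls lie between -34.3 and -22.8 and mutants between 27.2 and 30.8 on component 1, while component 2, with 16% of the variance, spreads the mutants from -29.9 to 24.1.

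The balance of higher and lower genes depends on the scaling. With library totals in place of TMM the median log2 fold change of all genes was -0.40, and 4801 genes were called, 293 higher and 4508 lower (6.10% higher against 49.3%). With the TPM table in limma the median was -0.48 and 7579 genes were called, 2.86% of them higher. Of the 949 genes that rose, 102 had a negative log2 fold change at library totals and 291 were still called higher, while that scaling moves all genes down and so cannot test those that fell. Leaving out a library also reduced the count of changed genes by over 1.5 times, to 886 without control replicate 1, 956 without control replicate 2, 1018 without control replicate 3 and 882 without mutant replicate 1. The major urinary protein genes took 2.33 ± 0.666% of the counts in the controls and 14.2 ± 2.35% in the mutants (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Mitochondrially encoded genes took 5.80 ± 0.188% and 4.78 ± 0.780% (exact permutation p = 0.2), ribosomal protein genes 0.986% and 0.998% (exact permutation p = 0.8), haemoglobin genes 0.0550% and 0.0390% (exact permutation p = 0.3), and the 10 most counted genes 17.3% and 20.9% (exact permutation p = 0.1). Albumin took 6.32% of the counts in the controls and 4.99% in the mutants (exact permutation p = 0.1).

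Many of the largest increases were in genes known to be expressed more in male than in female mouse liver. The major urinary protein genes Mup1, Mup2, Mup7, Mup11, Mup12, Mup15 and Mup17 were among the 12 with the largest increase. They encode pheromone carriers secreted by the male liver. Obp2a, an odorant-binding relative that is not a Mup gene, was also among the 12. Mup7 rose from 511 ± 683 to 29585 ± 6119 CPM and Mup1 from 30.2 ± 23.6 to 2668 ± 689 CPM, where control replicate 1 stood above the other controls (Mup7 with 1297, 166 and 68.4 CPM and Mup1 with 57.4, 18.4 and 14.8 CPM in control replicates 1 to 3). Without control replicate 1 the log2 fold changes were 7.98 for Mup7 and 7.33 for Mup1, against 5.86 and 6.46. The family of 22 genes summed rose 8.02-fold (log2 fold change 3.00 ± 0.22, edgeR adjusted p = 2.6e-04). Serpina1e, a member of the α1-antitrypsin family of protease inhibitors on chromosome 12 (103946931 to 103958975), rose from 109 ± 48.0 to 8344 ± 2505 CPM (log2 fold change 6.26 ± 0.44, adjusted p = 2.5e-04), and the summed Serpina1 family rose 2.88-fold. Hsd3b5, a male-specific steroid dehydrogenase, rose by a log2 fold change of 5.91 ± 0.73. Here too control replicate 1 stood above the other controls (3.42, 0.449 and 0.540 CPM in control replicates 1 to 3). Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway, rose from 51.6 ± 1.56 to 326 ± 71.2 CPM, and Gstp1, a glutathione transferase, from 513 ± 19.1 to 2108 ± 234 CPM. Of 23 tested members of the list of male-biased genes, 18 rose, 0 fell and 5 did not pass, with 18 also adjusted over the list alone and a median log2 fold change of 2.04. The list's call held with an estimated correlation (camera adjusted p = 0.0134), and its median was 1.64 at library totals.

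The largest increase among the named genes was in Moxd1, which is not in the list of male-biased genes. Moxd1, a monooxygenase-like gene on chromosome 10 (ENSMUSG00000020000.7, 24223517 to 24302790), had 0 counts in the 3 controls and 48.9 ± 17.4 CPM in the mutants, at least 2259-fold higher by the floor of 3 counts over the group. Acsm2, a medium-chain acyl-CoA synthetase, rose from 0.0442 to 1.36 CPM. Mup16 (log2 fold change 3.01 ± 0.13) and Tedc2 (2.55 ± 0.12, from 21.9 ± 2.48 to 128 ± 6.58 CPM), which encodes a partner of delta and epsilon tubulin, were among the 5 increases with the smallest p.

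Genes known to be higher in female liver included several of the largest decreases. Cyp2b9, a cytochrome P450, fell from 175 ± 81.2 to 1.31 ± 1.55 CPM (log2 fold change -7.09 ± 0.81, adjusted p = 0.00164), and Cyp2a4, a steroid hydroxylase, from 22.0 ± 11.7 to 0.133 ± 0.180 CPM, while the Cyp2a family summed did not pass (log2 fold change -0.02 ± 0.18, edgeR adjusted p = 0.963). The mutant means rest largely on mutant replicate 2, for Cyp2b9 with 0.131, 3.07 and 0.742 CPM in mutant replicates 1 to 3. For Cyp2a4 the values were 0.0262, 0.341 and 0.0322 CPM. Without mutant replicate 2 the log2 fold change of Cyp2b9 was -8.74. Hao2, a peroxisomal hydroxyacid oxidase, had 2.19 ± 1.38 CPM in the controls and 0 counts in the mutants, at least 73.7-fold lower. Of 17 tested female-biased genes 6 fell, 2 rose and 9 did not pass, and adjusted over the list alone 7 fell and 2 rose. The list passed against other genes (camera adjusted p = 0.00282), but not with an estimated correlation (adjusted p = 0.101), at library totals (0.125) or without the genes it shares with other lists (0.5995), where its median turned from -0.39 to 0.47.

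**Figure D2:**
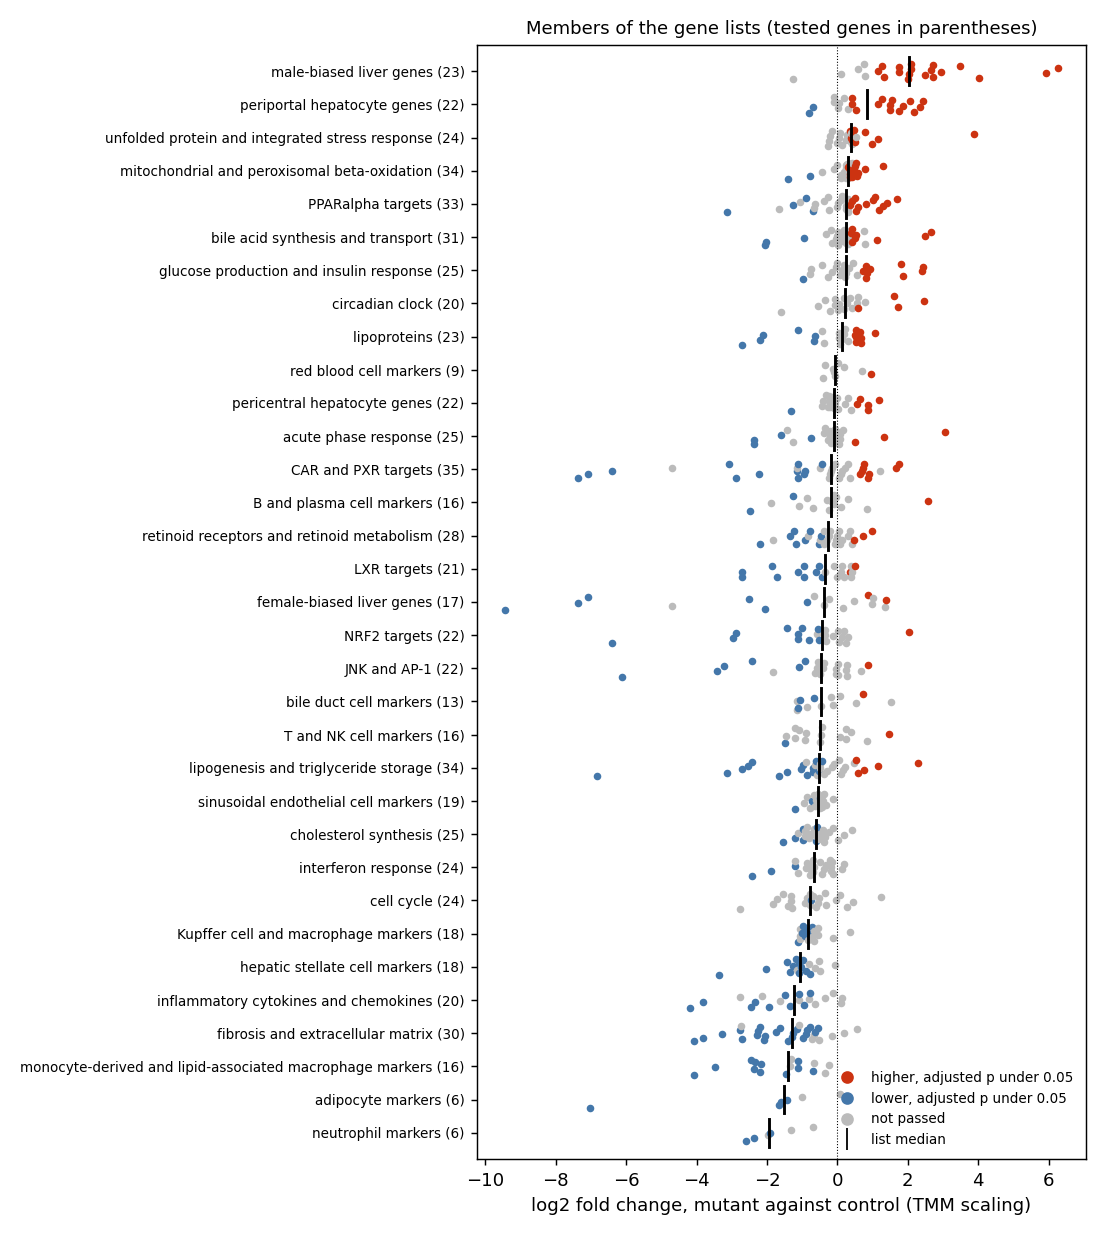
Log2 fold change of mutant against control (horizontal axis, TMM scaling) for each tested member of 33 gene lists (vertical axis, number of tested members in parentheses), with called members in colour, others in grey, and the list median as a bar. Male-biased genes lie highest with a median of 2.04 and neutrophil markers lowest with -1.94. Hao2, with 0 counts in the mutants, is drawn at its fitted value of -9.44, and library totals move the median of all genes to -0.40, which puts the medians of the lists from the unfolded protein response down to the lipoproteins below 0.

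Targets of the partner receptors of RXRα changed in different directions. Among 33 tested PPARα targets 12 rose, 4 fell and 17 did not pass (16 and 6 adjusted over the list alone). The fatty acid hydroxylases Cyp4a10 (1181 ± 242 to 3130 ± 129 CPM) and Cyp4a31 (29.0 ± 5.24 to 92.9 ± 5.01 CPM) and the peroxisomal bifunctional enzyme Ehhadh (609 ± 87.9 to 1486 ± 177 CPM) rose, and the fatty acid transporter Cd36 fell from 315 ± 34.4 to 35.7 ± 10.6 CPM (log2 fold change -3.14 ± 0.22, adjusted p = 2.5e-04). The summed Cyp4a family rose 2.30-fold. The list's call (camera adjusted p = 0.0106) was lost with an estimated correlation (adjusted p = 0.434), at library totals (0.242, median -0.14 against 0.26, 6 members higher and 13 lower) and without mutant replicate 2 (0.192).

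Of 34 tested genes of fatty acid oxidation 15 rose, among them Ehhadh and the electron transfer flavoprotein subunit Etfb (187 ± 10.1 to 320 ± 16.6 CPM), whose log2 fold change of 0.77 was 0.18 and not called in the limma fits on TPM. The peroxisomal transporter Abcd2 fell by 1.42 on the log2 scale, and of the list 2 fell and 17 did not pass. Adjusted over the list alone 24 rose and 2 fell. The list's adjusted p was 2.2e-06 with camera and 0.137 with an estimated correlation. At library totals 2 members were called higher and 6 lower, the list's adjusted p was 0.0541 and its median was -0.09 in place of 0.30.

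Of 21 tested LXR targets, 10 fell, 2 rose and 9 did not pass (10 and 4 adjusted over the list alone). The stearoyl-CoA desaturase Scd1 fell from 7769 ± 1170 to 1185 ± 560 CPM, the phospholipid transfer protein Pltp from 155 ± 42.7 to 23.7 ± 4.72 CPM and the GTPase Arl4c by 1.85 on the log2 scale. For this list the adjusted p was 3.2e-04 with camera, 0.103 with an estimated correlation and 0.185 without genes that stand in several lists.

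Of 35 tested CAR and PXR targets 12 fell, 8 rose and 15 did not pass (13 and 10 adjusted over the list alone). Cyp2b9 and Cyp2a4 are also in this list, in which the glutathione transferase Gstm3 fell from 28.7 ± 6.24 to 3.87 ± 0.696 CPM and Cyp2c38 fell by 2.24 on the log2 scale. The summed Cyp2b family was 127-fold lower in the mutants, a fold that depends on mutant replicate 2 (0.131, 3.35 and 0.807 CPM in mutant replicates 1 to 3), and the summed Cyp3a family 2.22-fold lower. Against other genes the adjusted p was 0.0147 with camera and 0.262 with an estimated correlation, and without the genes of several lists the direction reversed (median 0.13, adjusted p = 0.5995).

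Bile acid genes were divided: 8 of 31 rose, 3 fell and 20 did not pass (10 and 3 adjusted over the list alone). Cyp7b1 and the bile acid sulfotransferase Sult2a8 (431 ± 53.3 to 936 ± 78.6 CPM) rose, and the efflux pumps Abcb1a and Abcc3 fell by 2.05 and 0.95. As a group they had an adjusted p of 0.00725 with camera and 0.280 with an estimated correlation, and the call was lost without mutant replicate 3 (0.0537) and at library totals (0.0784, median -0.14 against 0.25, 3 members higher and 8 lower). Of 28 tested genes of retinoid handling, 8 fell, 3 rose and 17 did not pass (11 and 6 adjusted over the list alone). The retinol saturase Retsat (786 ± 105 to 1566 ± 156 CPM) and the plasma retinol carrier Rbp4 (2442 ± 156 to 4027 ± 431 CPM, not called in the limma fits on TPM with a log2 fold change of 0.12) rose, and the retinol esterifying enzyme Lrat, which is made by stellate cells, fell by 1.33. This list did not pass against other genes (camera adjusted p = 0.0715, with an estimated correlation adjusted p = 0.173) except at library totals (0.00873, 2 members higher and 16 lower). It passed with fry (adjusted p = 0.00507).

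Of 34 tested genes of lipid synthesis and storage 15 fell, 5 rose and 14 did not pass (18 and 6 adjusted over the list alone), and the list's call held with an estimated correlation (camera adjusted p = 0.0393). The lipid droplet proteins Plin4 (72.2 ± 18.3 to 13.3 ± 3.32 CPM) and Cidea (9.32 ± 9.47 to 0.0815 ± 0.0698 CPM), the monoacylglycerol acyltransferase Mogat1 (8.31 ± 1.61 to 1.41 ± 0.367 CPM), Cd36 and Scd1 all fell. For Cidea control replicate 3 stood above the other controls (4.57, 3.16 and 20.2 CPM in control replicates 1 to 3). The nuclear receptor Pparg, a driver of lipid storage, fell from 22.6 ± 3.54 to 8.39 ± 1.83 CPM. Of 6 tested adipocyte markers, several of which fat-laden hepatocytes also express, 4 fell, 0 rose and 2 did not pass (5 fell adjusted over the list alone), with an adjusted p of 0.0439 with an estimated correlation. Cfd, which encodes complement factor D, fell from 14.4 ± 8.03 to 0.107 ± 0.0392 CPM.

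Cholesterol synthesis genes had a median log2 fold change of -0.59. Of 25 tested genes 6 fell, 0 rose and 19 did not pass (13 fell and 1 rose adjusted over the list alone), with Acat2 (71.3 ± 5.94 to 36 ± 4.08 CPM) the one with the smallest p. The list's adjusted p was 1.6e-05 with camera and 0.401 with an estimated correlation. Lipoprotein genes were mixed, with 8 of 23 higher, 6 lower and 9 not passed (9 and 7 adjusted over the list alone). Apom rose from 79.9 ± 8.13 to 168 ± 20.8 CPM, and Apoc4 and Apoa5 rose by 0.67 and 0.64, increases that were no longer called in the limma fits on TPM. The list did not pass (camera adjusted p = 0.534, with an estimated correlation adjusted p = 0.547), and its median of 0.13, mean of -0.18 and upward test differed in sign. At library totals 2 members were called higher and 10 lower (median -0.27).

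Of 25 tested genes of glucose production and insulin response 9 rose, 1 fell and 15 did not pass (10 and 2 adjusted over the list alone). Pck1, the rate-limiting enzyme of gluconeogenesis, rose from 937 ± 135 to 3441 ± 1007 CPM, the alanine transaminase Gpt from 196 ± 11 to 354 ± 7.83 CPM, and the growth factor gene Igf1 from 308 ± 20.2 to 584 ± 24.1 CPM. The adjusted p was 1.0e-04 with camera and 0.101 with an estimated correlation, and the median of 0.23 was -0.17 at library totals, where 7 were called higher and 8 lower.

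Periportal hepatocyte genes, known to be higher near the portal vein, rose in 14 of 22 tested cases, with 2 lower and 6 not passed (15 and 2 adjusted over the list alone). The urea cycle enzymes Cps1 (1069 ± 25.9 to 4803 ± 1483 CPM) and Asl (191 ± 9.89 to 798 ± 204 CPM), the glutaminase Gls2 (94.8 ± 10.1 to 321 ± 53.2 CPM) and the IGF-binding protein Igfbp2 (175 ± 27.3 to 879 ± 176 CPM) rose. The median was 0.84 and stayed positive, 0.44, at library totals. For this list the adjusted p was 1.3e-14 with camera and 0.0700 with an estimated correlation. Pericentral genes did not pass as a list (camera adjusted p = 0.312, with an estimated correlation adjusted p = 0.539): 5 of 22 rose, 1 fell and 16 did not pass (6 and 1 adjusted over the list alone), and the median of -0.09 lay opposite to the mean of 0.05 and the upward test. At library totals 2 were called higher and 8 lower (median -0.48). Cyp1a2, a pericentral P450, rose from 132 ± 23.4 to 296 ± 62.9 CPM.

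Extracellular matrix and fibrosis genes fell as a group: 22 of 30 fell, 0 rose and 8 did not pass (24 fell and 1 rose adjusted over the list alone), with a median log2 fold change of -1.28. The call held with an estimated correlation (camera adjusted p = 0.0134). The collagen genes Col1a1 (34.6 ± 11.6 to 5.26 ± 0.949 CPM) and Col6a3 (19.6 ± 2.27 to 4.05 ± 0.221 CPM), the matrix protein gene Sparc (56.9 ± 6.24 to 18.3 ± 2.32 CPM) and the macrophage elastase Mmp12 (8.55 ± 1.16 to 0.505 ± 0.137 CPM) fell.

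Markers of most other liver cell types were lower or not called. Hepatic stellate cells, the vitamin A storing cells that make matrix, had 12 of 18 markers lower, 0 higher and 6 not passed (15 lower adjusted over the list alone). Dcn fell from 134 ± 10 to 77.8 ± 6.69 CPM, and Sod3 and Pdgfrb fell by 1.17 and 1.27. The list's adjusted p with an estimated correlation was 0.0700. Monocyte-derived and lipid-associated macrophages had 11 of 16 markers lower, 0 higher and 5 not passed (13 lower adjusted over the list alone), with a median of -1.41, and passed with an estimated correlation (adjusted p = 0.0393). Lgals3 (11.7 ± 1.63 to 2.29 ± 0.614 CPM), Cd63 (24.0 ± 6.42 to 4.38 ± 1.02 CPM) and the monocyte chemokine receptor Ccr2 (5.64 ± 1.27 to 1.08 ± 0.156 CPM) fell.

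Kupffer cells, the resident macrophages, had 7 of 18 markers lower, 0 higher and 11 not passed (13 lower adjusted over the list alone), with a median of -0.82. Against other genes the adjusted p was 3.6e-06 with camera and 0.282 with an estimated correlation. Cd68, a lysosomal marker, fell from 11.4 ± 2.20 to 5.24 ± 1.1 CPM, a call lost without control replicate 1 or control replicate 2. Sinusoidal endothelial markers had 3 of 19 lower, 0 higher and 16 not passed (4 lower adjusted over the list alone), a median of -0.54 and an adjusted p of 8.4e-04 with camera and 0.446 with an estimated correlation. Of 6 tested neutrophil markers 3 fell, 0 rose and 3 did not pass (5 fell adjusted over the list alone), with an adjusted p of 1.6e-04 with camera and 0.0700 with an estimated correlation. S100a8 (1.36 ± 0.0503 to 0.222 ± 0.142 CPM) lost its call on leaving out any control or mutant replicate 1. S100a9 (1.87 ± 0.563 to 0.498 ± 0.190 CPM) lost its call on leaving out any library. Lcn2, an iron-scavenging acute phase protein also made by hepatocytes, fell from 62.6 ± 26.3 to 12.1 ± 3.80 CPM.

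The other cell type lists did not pass against other genes with camera. With fry the B and plasma, T and NK, and bile duct lists passed (adjusted p = 0.00647, 0.0471 and 0.0138). B and plasma cell markers had 2 of 16 lower, 1 higher and 13 not passed, adjusted over the list alone as well (camera adjusted p = 0.175, with an estimated correlation adjusted p = 0.281). The immunoglobulin heavy chain Ighm fell from 15.9 ± 1.63 to 2.85 ± 0.959 CPM. T and NK cell markers had 1 of 16 lower, 1 higher and 14 not passed, again also adjusted over the list alone (camera adjusted p = 0.271, with an estimated correlation adjusted p = 0.446). Those were the chemokine gene Ccl5, with a call lost on leaving out any library except mutant replicate 3, and Cd4, lost on leaving out any library. Bile duct markers had 3 of 13 lower, 1 higher and 9 not passed (4 and 1 adjusted over the list alone), with a camera adjusted p of 0.0611 and 0.173 with an estimated correlation. That list passed without control replicate 1 (0.0342) and with the CPM filter (0.0266). Osteopontin, Spp1, fell from 66.8 ± 14.4 to 30.6 ± 8.05 CPM. Red blood cell markers had 1 of 9 higher, 0 lower and 8 not passed, adjusted over the list alone as well (camera adjusted p = 0.616, with an estimated correlation adjusted p = 0.820), with a median of -0.06 against a mean of 0.09, and the 1 was the haem synthesis gene Alas2, which was not called in the limma fits on TPM. Of the pancreatic acinar markers 0 were expressed enough to be tested.

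Among inflammatory mediators 10 of 20 tested cytokine and chemokine genes were lower, 0 higher and 10 not passed (15 lower adjusted over the list alone), with a median of -1.22. The monocyte attractant Ccl2 fell from 2.65 ± 0.758 to 0.185 ± 0.0241 CPM, interleukin 1β, Il1b, from 2.93 ± 0.510 to 0.532 ± 0.0907 CPM, and Cxcl10 and the adhesion molecule Icam1 by 2.33 and 1.09 on the log2 scale. As a group they had an adjusted p of 4.6e-08 with camera and 0.137 with an estimated correlation. Of 24 interferon-stimulated genes 3 fell, 0 rose and 21 did not pass, adjusted over the list alone as well (camera adjusted p = 0.00195, with an estimated correlation adjusted p = 0.452, at library totals 0.0596). Ifit2 fell from 10.1 ± 4.25 to 2.76 ± 0.219 CPM. Acute phase genes did not pass as a list except without control replicate 3 (camera adjusted p = 0.198 with all libraries, 0.00481 without it, and with an estimated correlation adjusted p = 0.700). There 3 of 25 rose, 4 fell and 18 did not pass, adjusted over the list alone as well. The iron hormone gene Hamp rose from 51.2 ± 23.5 to 427 ± 211 CPM, and Orm2 and the interleukin 1 antagonist Il1rn fell by 2.36 and 1.59.

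**Figure D3:**
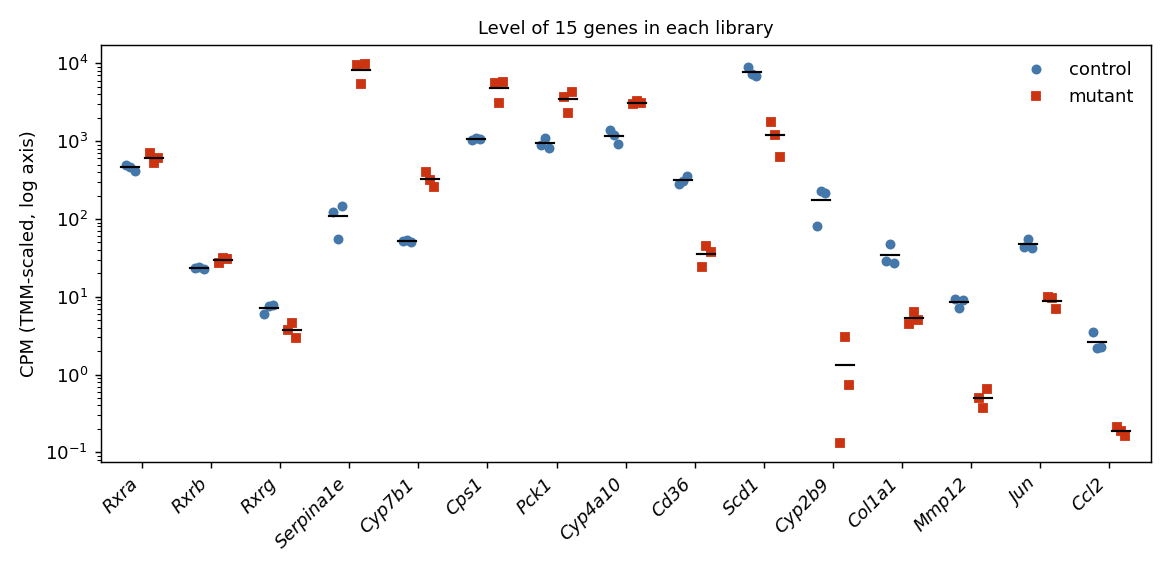
CPM after TMM scaling (vertical axis, log scale) of 15 genes in each library, circles for the 3 controls and squares for the 3 mutants, with the group mean as a bar. Rxra had 414 to 501 CPM in controls and 522 to 700 CPM in mutants, and from Serpina1e to Ccl2 the groups do not overlap.

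Genes of the JNK and AP-1 list, which holds the kinases of the stress pathway and its immediate early targets, had 6 of 22 members lower, 1 higher and 15 not passed (10 and 1 adjusted over the list alone). The members that fell with the smallest p were immediate early or feedback genes and not the kinases. The transcription factor Jun fell from 47.2 ± 7.51 to 8.82 ± 1.56 CPM, Atf3 from 8.29 ± 5.94 to 0.879 ± 0.176 CPM, and the phosphatase Dusp6 from 52.5 ± 7.49 to 24.6 ± 2.08 CPM. For Atf3 control replicate 2 stood above the other controls (5.35, 15.1 and 4.39 CPM in control replicates 1 to 3). Fosb had 123 counts over the controls and 1 over the mutants, a ratio of 92.5 (95% counting interval 16.3 to 3682). The adjusted p was 1.2e-04 with camera and 0.137 with an estimated correlation.

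Glutathione and antioxidant genes under NRF2 fell in 10 of 22 cases, with Gstp1 higher and 11 not passed (12 lower and 1 higher adjusted over the list alone). Gsta1 fell from 12.9 ± 1.23 to 0.161 ± 0.279 CPM, Gstm1 from 1239 ± 183 to 573 ± 56.2 CPM, and the summed Gstm and Gsta families were 2.02-fold and 1.47-fold lower. For this list the adjusted p was 1.2e-04 with camera and 0.161 with an estimated correlation. Genes of the unfolded protein and integrated stress responses rose in 10 of 24 cases, with 0 lower and 14 not passed (14 higher adjusted over the list alone). The asparagine synthetase Asns rose from 1.90 ± 0.463 to 28.1 ± 15.3 CPM and Herpud1, a part of ER-associated degradation, from 232 ± 26.2 to 515 ± 141 CPM. The chaperone Hsp90b1 had a log2 fold change of 0.47 that turned to -0.13 in the limma fits on TPM. Against other genes the adjusted p was 1.7e-05 with camera and 0.164 with an estimated correlation, and at library totals 3 members were called higher and 3 lower and the median of 0.39 was -0.01.

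Of 20 clock genes 4 rose, 0 fell and 16 did not pass, adjusted over the list alone as well. Per1 rose from 11.7 ± 0.125 to 35.6 ± 12.3 CPM. As a group they had an adjusted p of 0.0183 with camera and 0.147 with an estimated correlation, and the median of 0.23 was -0.17 at library totals. Of 24 cell cycle genes only Ccnd1, cyclin D1, fell (40.7 ± 6.00 to 24.1 ± 6.86 CPM), a call that was lost on leaving out any library except mutant replicate 1, and adjusted over the list alone 0 passed. That list's adjusted p was 0.0232 with camera, 0.137 with an estimated correlation, 0.0574 without mutant replicate 2, 0.640 at library totals and 0.350 with the CPM filter.

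Several large decreases belong to none of these groups. Sprr1a, a cornified envelope protein gene, and Rsph4a, a component of ciliary radial spokes, had 0 counts in the mutants and were at least 101-fold and 39.6-fold lower. Kif23, a mitotic kinesin, had 296 counts over the controls and 3 over the mutants, a ratio of 74.2 (95% counting interval 25.1 to 362). The organic anion transporter genes Slc22a29 and Slc22a27 fell by 5.03 and 4.54 on the log2 scale. The aquaglyceroporin Aqp7 fell by 5.04, a call lost without control replicate 3 (log2 fold change -3.21, adjusted p = 0.0518) or any mutant. Among the 5 decreases with the smallest p, the water channel Aqp8 fell from 119 ± 4.51 to 19.5 ± 2.97 CPM, the class I histocompatibility gene H2-Q1 from 26.0 ± 5.52 to 2.69 ± 0.342 CPM, Fam126a from 25.1 ± 1.38 to 5.55 ± 0.410 CPM and Tceal8 from 29.9 ± 4.78 to 4.38 ± 0.813 CPM. Over the 33 tested lists, 25 passed with the preset correlation, 8 upward and 17 downward, and 5 passed with an estimated correlation: male-biased genes, matrix, lipogenesis, monocyte-derived macrophages and adipocyte markers.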

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

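The alternatives with families summed, with library totals without the Mup genes and with genes of 1 list only were chosen after the data were seen. With library totals, 4801 genes and 1782 genes changed at least 2-fold were called. In the limma fits on TPM the counts were 7579 with a pseudocount of 1, 7526 with 0.1 and 6581 with no filter, and 1950 genes at least 2-fold with 0.1. Leaving the Mup genes out of the table and totals gave 2364 genes and moved the median of all genes from -0.40 to -0.21, so the Mup share accounts for part of that shift and the cause of the rest was not tested. RLE, robust and DESeq2 fits, both other filters and summed families gave 1898 to 2607 genes. Leaving out libraries gave 882 to 1514 genes and 495 to 735 at least 2-fold, with fewer libraries tested.

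Same-numbered libraries of the groups did not deviate together (correlations 0.02, -0.003 and 0.06), which gives no sign of pairing. With the replicate number as a block 1558 genes were called, of which 1423 were shared with the fit without it, and 0 lists lost their call. Under the block 7 named genes lost their call and 1 gained one. Those lost include Rxrg (edgeR adjusted p = 0.0516), Ccl5 (0.0732), Cd4 (0.0899) and Ccnd1 (0.0707). For Rxra the log2 fold change was 0.404 with no filter and 0.403 with DESeq2, both called, and 0.291 to 0.496 on leaving out libraries. In limma it was -0.1985 (pseudocount 1, with and without a filter) and -0.1997 (0.1). The deposited counts differ from TPM only by a factor per gene and a factor per library, so for a given gene these fits differ mainly in library scaling. Other named genes moved down alike with a pseudocount of 1: Etfb from 0.773 to 0.176, Rbp4 from 0.722 to 0.122 and Hsp90b1 from 0.470 to -0.127. The turn of Rxra therefore goes with the scaling and is no separate evidence of a decrease. Its increase depends on the scaling as well, since before scaling Rxra had 62397 counts over the controls and 62496 over the mutants. Other reversals were Rxrb (-0.04781 at library totals, -0.2357 and -0.2485 in limma), Hsp90b1 (-0.127 in the limma fits) and, with genes of 1 list only, the medians of the CAR and PXR list (0.134) and the female-biased list (0.467, not past the threshold). The number of lists past the threshold fell from 25 to 5 with an estimated correlation and was 23 to 26 on leaving out libraries. With fry 24 lists passed. Retinoid handling (fry adjusted p = 0.00507), B and plasma cell (0.00647), bile duct (0.0138), and T and NK cell markers (0.0471) gained a call. PPARα targets (0.0828), cholesterol synthesis (0.112), interferon response (0.191), Kupffer cell (0.0604) and sinusoidal endothelial markers (0.154) lost theirs. In TPM the shares differed between groups by 20.9 percentage points for Mup genes, -2.72 for mitochondrially encoded, -0.378 for ribosomal protein, -0.0777 for haemoglobin and 8.26 for the 10 most counted genes, since TPM weights short genes more.

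Over all named genes but Rxra, 2260 results kept direction and side of the threshold, 178 lost their call, 39 gained one and 7 reversed, which are those of Rxrb and Hsp90b1 above. In all limma fits on TPM the increases of Etfb (0.176 with a pseudocount of 1), Rbp4 (0.122), Alas2 (0.347), Apoa5 (0.0436) and Apoc4 (0.0771) lost their call, and Apoa5 lost it at library totals too. With no filter those fits also lost Per1, Herpud1, Cyp1a2, Retsat and Aqp7. After TMM scaling 1 CPM is 31.0 to 46.0 counts. In simulated data, where 200 of 14286 genes were changed, 45.2% of 2-fold changes were recovered over all levels. Far more genes, 1923, were called in the data, so the recovery there may differ. How far depth limits the recovery was not separated from the spread between libraries.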

Other observations

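The tests for female controls, for paralogs, for cell shares, for the segment at Rxra and for predicted genes counted singly, and the gene lists and genes outside the naming rule in these paragraphs, were chosen only after the results were seen. Transcripts of nitrogen disposal enzymes were higher in the mutants. All 8 urea cycle genes rose, with a median log2 fold change of 1.11 (0.72 at library totals) and an adjusted p of 0.0179 with camera and an estimated correlation, adjusted over the 4 lists added. Beside Cps1 and Asl these include Ass1 (1.49 ± 0.17) and Arg1 (1.26 ± 0.14). Of 46 genes of amino acid breakdown 34 rose, 0 fell and 12 did not pass (39 rose adjusted over the list alone), with a median of 0.84 (0.44 at library totals) and an adjusted p of 0.0179 with an estimated correlation. The glutamate transaminase Got1 (2.39 ± 0.34), serine dehydratase Sds (2.44 ± 0.35) and cystathionine gamma-lyase Cth (1.76 ± 0.28) were among those that rose. These lists share genes with the periportal list and were drawn up because its members had risen, so they are not independent evidence.

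Genes of liver-made complement and coagulation proteins rose in 16 of 33 cases, with 0 lower and 17 not passed (23 and 2 adjusted over the list alone). Their camera adjusted p was 0.0305 with an estimated correlation, and their median of 0.34 was -0.06 at library totals. C8b, a subunit of the membrane attack complex, rose from 61.7 ± 12.3 to 280 ± 16.6 CPM. Among 18 genes known to respond to glucocorticoids 10 rose, 0 fell and 8 did not pass (10 and 1 adjusted over the list alone), with a median of 0.93 (0.53 at library totals) and an adjusted p of 0.0833 with an estimated correlation. Fkbp5, a feedback regulator of the glucocorticoid receptor, rose from 20.1 ± 3.91 to 110 ± 37.0 CPM and Zbtb16 from 2.49 ± 0.562 to 30.1 ± 14.9 CPM. The labels used here give neither the hour of sampling, the feeding state nor the body weight of the animals.

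Male-biased genes were higher and several female-biased genes lower in the mutants. Female animals among the controls are argued against, since the control library with the lowest summed CPM of 4 Y-linked genes had 91.2% of the mutant mean and Xist had at most 1 count in any library. Scaling is argued against as the whole cause, since 17 of the 18 genes stayed called higher at library totals. Reads shared between paralogs are argued against too, since 6 of 10 members outside multigene families rose. The biological difference between the groups stays open as the cause, and no test here tells the Rxra change apart from diet response or feeding state.

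Many matrix and macrophage genes were lower in the mutants, and so were adipocyte markers. Sinusoidal endothelial markers served as the reference, although their own mean log2 CPM overlapped between groups (3.50 in control replicate 2, 3.78 in mutant replicate 3). A lower share of every non-hepatocyte cell type would lower all their markers alike. It is argued against as the whole cause for matrix genes, whose mean log2 CPM fell relative to that of the sinusoidal endothelial markers (-0.953 ± 0.350, exact permutation p = 0.1, the smallest possible). The same holds for markers of monocyte-derived macrophages (-1.15 ± 0.41) and neutrophils (-1.32 ± 0.46), each with exact permutation p = 0.1. These lists had no overlap between groups. Adipocyte markers fell likewise (-1.50 ± 0.31, exact permutation p = 0.1, no overlap). Hepatocytes also express several of them, so their fall does not bear on this explanation. For Kupffer cell (-0.22 ± 0.39, exact permutation p = 0.5) and stellate cell markers (-0.54 ± 0.29, exact permutation p = 0.2) the groups overlapped. They overlapped too for T and NK cell (0.07 ± 0.35), B and plasma cell (0.25 ± 0.34) and bile duct markers (0.16 ± 0.44). For the lists with overlap the explanation stays open. Adipose tissue attached to the control livers is argued against for the adipocyte markers, since Adipoq counts were 0% of Cfd counts in the controls (0 against 1953), where fat would bring both. The gene values do not separate the number of matrix-making cells and macrophages from their activity, and either could differ.

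Some genes were near absent in 1 group: 42 called genes differed by at least 16-fold with a CPM of at least 1, of which 20 were higher, 10 of them Mup genes, and 22 lower. A strain segment carried along with the Rxra allele is argued against as the main cause, since 1 of the 42 genes, Obp2a, lay within 15 Mb of Rxra, and 16.3% of the 252 tested genes there were changed against 13.4% elsewhere (Fisher's exact test over genes, which are not independent replicates, p = 0.192). For strain segments elsewhere, with 1 gene kept per symbol stem, 2 pairs of 24 genes lay within 2 Mb, where 10000 random draws gave a median of 1 and reached 3 at the upper end of their central 95%. The count lies between that median and that upper end, so it leaves this explanation open. Of these pairs 1, Cidea with B430212C06Rik, overlaps in the genome and can share reads, which weakens the count as a sign of segments. Counting predicted genes singly gave 6 pairs among 30 genes. Random draws gave a median of 1 and reached 4 at the upper end of their central 95%, so this count lay above them. That test is void, however, because the pairs it adds are between neighbouring genes of equal length or of 1 gene family, which can share reads. Among them Gm7969 had 0 CPM in the mutants (log2 fold change -10.4). Its neighbours Gm48419 and Gm48423 had 0 CPM in the controls (log2 fold change 8.67 each). The cause of this switch in opposite directions was not tested, and strain segments elsewhere stay open.

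With 3 libraries against 3 there are 10 splits of the 6 libraries, too few for a share under 0.05. The real split alone, 1 of the 10, gave as many as 1923 changed genes, and the highest of the others was 0. For genes changed at least 2-fold the real split gave 825, also reached by 1 split, and the highest other was 0. For gene lists past the threshold with the preset correlation the real split gave 25, again reached by 1 split, and the highest other was 16. Every other split sets libraries of both groups on each side, so it still carries part of the group difference. The lists it calls can reflect that difference. The same mixing widens the spread within a side, which holds down the count of genes. Neither count therefore measures what chance gives.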
